A study of Homo sapiens with 8 samples.

How the data were processed

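Total RNA of 786-O cells treated for 6 h with 25 μM pentamidine or with DMSO was labelled with biotin and hybridised to Affymetrix expression arrays of 2 types, per the labels' protocols. Each array type had 2 DMSO and 2 pentamidine arrays. The deposited values are linear probe set intensities. The arrays were processed with Affymetrix Expression Console, per the submitters' processing notes. The version, algorithm and filters are not given in the sources used here. In the deposited intensity tables the mean after trimming 2% from each end was 500.2 on each array of the first type and 500.1 on each of the second, and the medians ranged from 75.6 to 88.2 and from 135 to 164.

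The annotation given for each array type listed 1 gene symbol for 19730 of 22277 probe sets of the first type and 13588 of 22665 of the second, several for 568 and 212, and none for 1979 and 8865. Symbols were updated by gene ID to a RefSeq gene table for assembly GRCh38.p14, which 19713 and 13548 probe sets matched. A gene was represented by its probe set with the highest mean among those kept.

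Tests, filters, gene lists and the rule for naming genes were chosen before the data were examined. Affymetrix control probe sets, 62 and 88, were left out. Intensities were taken as log2(value + 16), and probe sets with a mean under the 30th percentile of their table were left out, which kept 15550 and 15804. Pentamidine was compared with DMSO within each array type by lmFit and eBayes of limma 3.58.1 in R 4.3.3, without a block, at a Benjamini-Hochberg adjusted p under 0.05. The array types were not pooled, since the labels do not say whether the second type carried other cultures. With 2 arrays against 2 the smallest 2-sided exact p for a single value is 0.333, so no exact test was made.

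Genes named in the text were to be the 12 highest and 12 lowest by log2 fold change past the threshold on the first array type, and the 6 and 6 on the second, with groups that do not overlap. As none passed, the same numbers were taken by the largest absolute moderated t of limma. Up to 4 members of a list were named by the same statistic. Dim means under the median mean level of the probe sets tested.

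The 30 gene lists covered p53 targets, the integrated stress response, ER chaperones, heat shock, NRF2, metallothioneins, cholesterol synthesis, lysosome and autophagy, polyamines, G2/M and mitosis, G1/S, hypoxia-inducible factor targets, NF-kB, interferon, immediate-early and MAPK feedback genes, TGF-beta, YAP, histones, DNA repair, ribosome biogenesis, oxidative phosphorylation, glycolysis, apoptosis, short-lived transcripts, reported pentamidine targets, renal epithelial identity, and leukocyte, endothelial, stromal and erythroid markers. Lists with at least 5 tested genes, 26 and 11, were tested with limma's camera at a preset correlation of 0.01. Members were also adjusted over the list alone, with no further adjustment over the lists.

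The fits were tested on simulated data: 20 simulations per array type, each with 200 probe sets changed by 1.5-fold to 8-fold. The fixed fit made 2 false calls over all simulations of the first type and 0 for the second, and the trend fit 142 and 57. Alternatives were quantile normalization, median centring, other filters, an offset of 1, a variance trend, a robust prior, a replicate block, other thresholds, adjustment over both types, leaving out each array, and for lists an estimated correlation, fry, the median over probe sets, and members that no other list holds. A 60th percentile filter, for lists also with an estimated correlation, a larger offset and the trend with the robust prior were added after the data were seen.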

Results

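Gene expression was measured in 786-O cells, an established human renal cell carcinoma line without functional VHL, after 6 h in 25 μM pentamidine or in its vehicle, DMSO. Pentamidine is an aromatic diamidine used against protozoal and Pneumocystis infections, and it binds the minor groove of AT-rich DNA. Total RNA was hybridised to Affymetrix expression arrays of 2 types, with 2 DMSO and 2 pentamidine arrays on each. The labels call the samples biological duplicates. They do not say whether the arrays of the second type carried the same RNA as those of the first, so each type was tested alone. The first array type held 22277 probe sets and the second 22665. The trimmed mean intensity was 500.2 on every array of the first type and 500.1 on every array of the second. Array pairs of the first type correlated at 0.971 to 0.984 over log2 values across probe sets, and those of the second type at 0.820 to 0.859, so no pair held identical values. The number of arrays, 2 per group, limits the precision of every value.

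The first comparison asked which transcripts differ between pentamidine and DMSO on the first array type. No gene passed the test, and 98.9% of the probe sets above the median level lay within 1.5-fold of DMSO. The list of metallothioneins, the small metal-binding proteins, and zinc genes lay above DMSO in 7 of 8. The gene below was SLC30A1, which is not a metallothionein, at -0.02. On the second array type another probe set of SLC30A1 gave 0.43 (95% interval -0.41 to 1.26). The list's median log2 fold change was 0.15, which quantile normalization took to 0.08. By limma's camera the list's unadjusted p was 0.0248 with the preset correlation and 0.146 with an estimated one. Its genes are thus not separate signals. Mitotic genes lay below DMSO in 13 of 19, with a median of -0.08. Transcripts of the inflammatory cytokine TNF measured 117 and 129 intensity units in DMSO and 72.9 and 44.0 in pentamidine, a log2 fold change of -0.93 (95% interval -1.58 to -0.27, n = 2 per group) that did not pass. Of 15550 probe sets tested with limma, 0 passed an adjusted p of 0.05 and the smallest adjusted p was 0.926, while 747 had an unadjusted p under 0.05 where chance gives 777.5. The 747 were 482 above and 265 below DMSO, but 307 above and 412 below after quantile normalization and 270 above and 375 below without pentamidine array 1. Without DMSO array 2 the count was 1339. The DMSO and pentamidine arrays did not overlap for 35.2% of probe sets, where chance gives 33.3%.

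None of the 12 genes above and 12 genes below DMSO named by the fixed rule passed, and each had a limma adjusted p of 0.926. The 12 above DMSO were all dim, so their fold changes depend on the offset added before the log. PPP1R14D, an inhibitor of protein phosphatase 1, measured 0.906 and 3.13 units in DMSO and 59.4 and 45.4 in pentamidine (log2 fold change 1.92, 95% interval 1.42 to 2.42, or 0.71 to 3.13 with a variance trend), and with a larger offset its log2 fold change was 0.47. FGA, the fibrinogen alpha chain, had a log2 fold change of 1.60, IL23A, a subunit of interleukin 23, 1.51, and KLRG1, a lymphocyte receptor, 1.61. GPM6B, SCN8A, CELF2, SPON1, CDX1, SPOCK2, CLEC11A and KDM5C had values from 0.99 to 1.54. Another probe set of SPON1 went the other way. Of the 12 below DMSO, 11 were dim, with the same dependence: OR2H2, an olfactory receptor, had a log2 fold change of -1.65 (-0.42 with a larger offset), NUDT18 -1.56, MOGAT2 -1.20, POMT2 -1.51, GAB1 -1.36 and SSX2 -1.30, and 2 other probe sets of SSX2 went the other way. CCDC57, ZNF213-AS1, CEBPE and H2AC25 lay between -1.25 and -0.92, and EGR3, an immediate-early transcription factor, at -1.30. The bright one was ANKRD13C-DT, a long non-coding RNA, at 574 and 517 units in DMSO and 322 and 298 in pentamidine (log2 fold change -0.78, 95% interval -1.22 to -0.35). On the second array type ANKRD13C-DT went the other way, at 0.17 by another probe set.

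Stress response genes lay on both sides of DMSO. Of 24 genes of the integrated stress response, the ATF4 program of amino acid supply, 11 lay above and 13 below, with a median log2 fold change of -0.04. SLC7A5, a large neutral amino acid transporter, had -0.48, CEBPB -0.34, NUPR1 -0.59 and ATF3 0.36. ER chaperone and ER-associated degradation genes lay above DMSO in 5 of 15 (median -0.08), with SEC61B at -0.42, EDEM1 at -0.30, HERPUD1 at -0.25 and CALR at -0.30. The p53 targets lay above in 12 of 20 (median 0.04), with MDM2 at 0.51, XPC at 0.47, GDF15 at 0.28 and BBC3 at -0.27. Cytosolic heat shock genes lay above in 7 of 14 (median 0.01), with BAG3 at 0.18 and HSPE1 at -0.22. NRF2 genes lay above in 10 of 13 (median 0.07), with GCLC at 0.24 and AKR1B10 at -0.42. Among the metallothioneins, MT1G had 0.32 (95% interval -0.08 to 0.72), MT1H 0.28, MT1F 0.18 and MT2A 0.17. Apoptosis regulators lay above in 12 of 19 (median 0.07), with XIAP at 0.68, BIK at 0.33, BCL2A1 at -0.33 and BCL2 at -0.62.

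Genes of growth and division lay on both sides of DMSO. In the mitotic list, BUB1B had a log2 fold change of -0.36, CCNB1 -0.29, AURKB -0.24 and BIRC5 -0.26. Genes of G1/S and DNA replication lay above DMSO in 7 of 20 (median -0.05), with E2F1 at 0.38, and DNA repair genes in 8 of 19 (median -0.04), with CHEK2 at -0.33. Histone genes lay above in 5 of 7 (median 0.16), with H2BC21 at 0.74 and H4C8 at -0.44. Ribosome biogenesis genes lay above in 11 of 18 (median 0.02, while the mean of -0.04 and the list test pointed down). Within them RRS1, a factor of large subunit assembly, had -0.61, NOP56 -0.45, RRP9 -0.47 and POLR1B, a subunit of RNA polymerase I, 0.75. The POLR1B probe set was dim, and another one on the second array type gave -0.29. Nuclear genes of oxidative phosphorylation lay above in 9 of 21 (median -0.01), with COX5A at -0.15, and glycolysis genes in 11 of 16 (median 0.09), with GAPDH at 0.30 and ALDOC at 0.79. Polyamine genes lay above in 7 of 15 (median -0.02, while the mean of 0.08 and the list test pointed up), with ARG2 at 0.86 and SMOX at -0.43. Cholesterol synthesis genes lay above in 11 of 17 (median 0.07), with MVK at 0.45 and CYP51A1 at 0.30. Lysosome and autophagy genes lay above in 15 of 21 (median 0.06), with UVRAG at 0.43 and FLCN at -0.35.

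Signalling targets were likewise mixed. Of 23 NF-kB and inflammatory genes, 11 lay above DMSO (median -0.05), with TRAF1 at -0.77, the chemokine CXCL2 at -0.54 and IL1B at 0.52. Interferon-stimulated genes lay above in 14 of 18 (median 0.11), with IFIT1 at 0.35, IFIT2 at 0.31 and IFI44 at -0.32. Immediate-early and MAPK feedback genes lay above in 12 of 19 (median 0.06, mean -0.03), with JUN at 0.43, MYC at 0.33 and IER2 at -0.30. Hypoxia-inducible factor targets lay above in 11 of 22 (median -0.00, mean 0.03), with CXCR4 at 0.64, PDK1 at 0.49 and NDRG1 at -0.35. TGF-beta and matrix genes lay above in 7 of 17 (median -0.03), with SMAD7 at -0.36, and short-lived transcripts in 16 of 29 (median 0.01), with SGK1 at 0.50. YAP targets lay above in 3 of 11 (median -0.07, mean 0.02). Among them ANKRD1, a muscle ankyrin repeat protein, measured 31.2 and 37.5 units in DMSO and 79.0 and 73.8 in pentamidine (log2 fold change 0.88, 95% interval 0.44 to 1.31, or 0.07 to 1.68 with a variance trend). In the fit fixed beforehand, ANKRD1 was the only gene of any list to pass when adjusted over the list alone, with limma at 0.0472, and it did not pass over all probe sets or over the list in a fit with a variance trend, in which RRS1, NOP56, SLC7A5 and CXCL2 did. Genes whose products pentamidine is reported to act on lay above in 7 of 9 (median 0.23), with S100A1 at 0.70, TOP1 at 0.23 and the phosphatase PTP4A1 at -0.37. Renal epithelial genes lay above in 6 of 15 (median -0.06), with LHX1 at 0.69 and PAX2 at -0.50.

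No list was called on the first array type. Over 26 lists, limma's camera gave adjusted p values from 0.331, for the metallothionein and the mitotic lists, to 0.964, and none was under 0.846 with an estimated correlation. Marker lists of other cell types had fewer than 5 genes past the filter and were not tested: 3 leukocyte genes, 1 endothelial gene, 4 stromal genes and 1 erythroid gene passed the filter, with median log2 fold changes of -0.12, 0.30, -0.12 and -1.05. In simulated data, limma as fitted here found 0% of 2-fold changes, 35.2% of 4-fold and 85.9% of 8-fold changes among probe sets above the median level. A simulated list shifted by 0.5 was called in 20 of 20 simulations. The simulated genes were drawn independently, and 0.5 is larger than any list median on this type (up to 0.23). That count therefore says little about smaller shifts or correlated genes. The brightest 2% of probe sets leaned upward: they had a median log2 fold change of 0.14, and 0.00 after quantile normalization.

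The variance of these arrays depended on the level, and a limma fit with a trend of the variance in mean level also gave 0 probe sets past the threshold, with 798 at an unadjusted p under 0.05. In simulated data that fit found 76.8% of 2-fold changes among above-median probe sets. Its 95% interval lay inside a 2-fold change for 97.9% of the 7775 above-median probe sets, and for 42.8% of the dimmer ones.

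**Figure D1:**
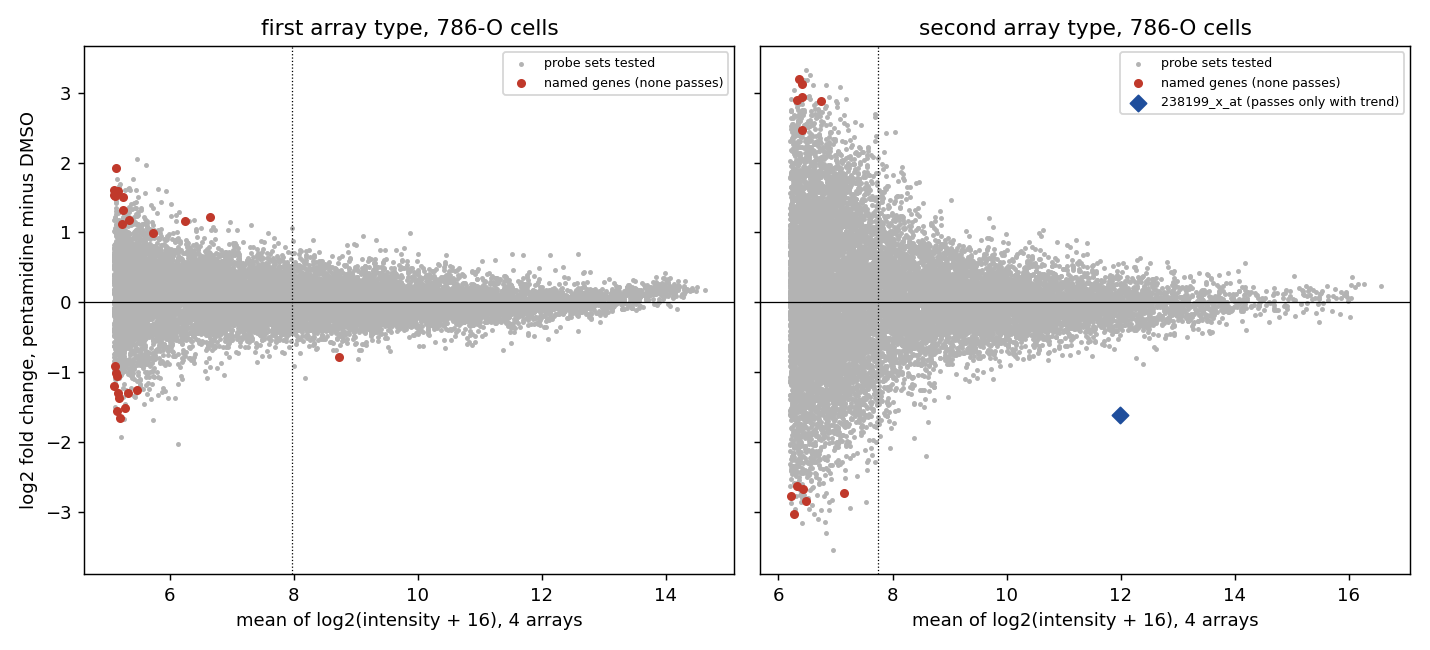
Log2 fold change, pentamidine minus DMSO, against the mean of log2(intensity + 16) over 4 arrays, with 1 grey point per probe set tested, red points for the genes named by rule, and a dotted line at the median level. The spread is widest among dim probe sets, and on the second array type the diamond, 238199_x_at, stands apart among the bright ones at -1.61.

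**Figure D2:**
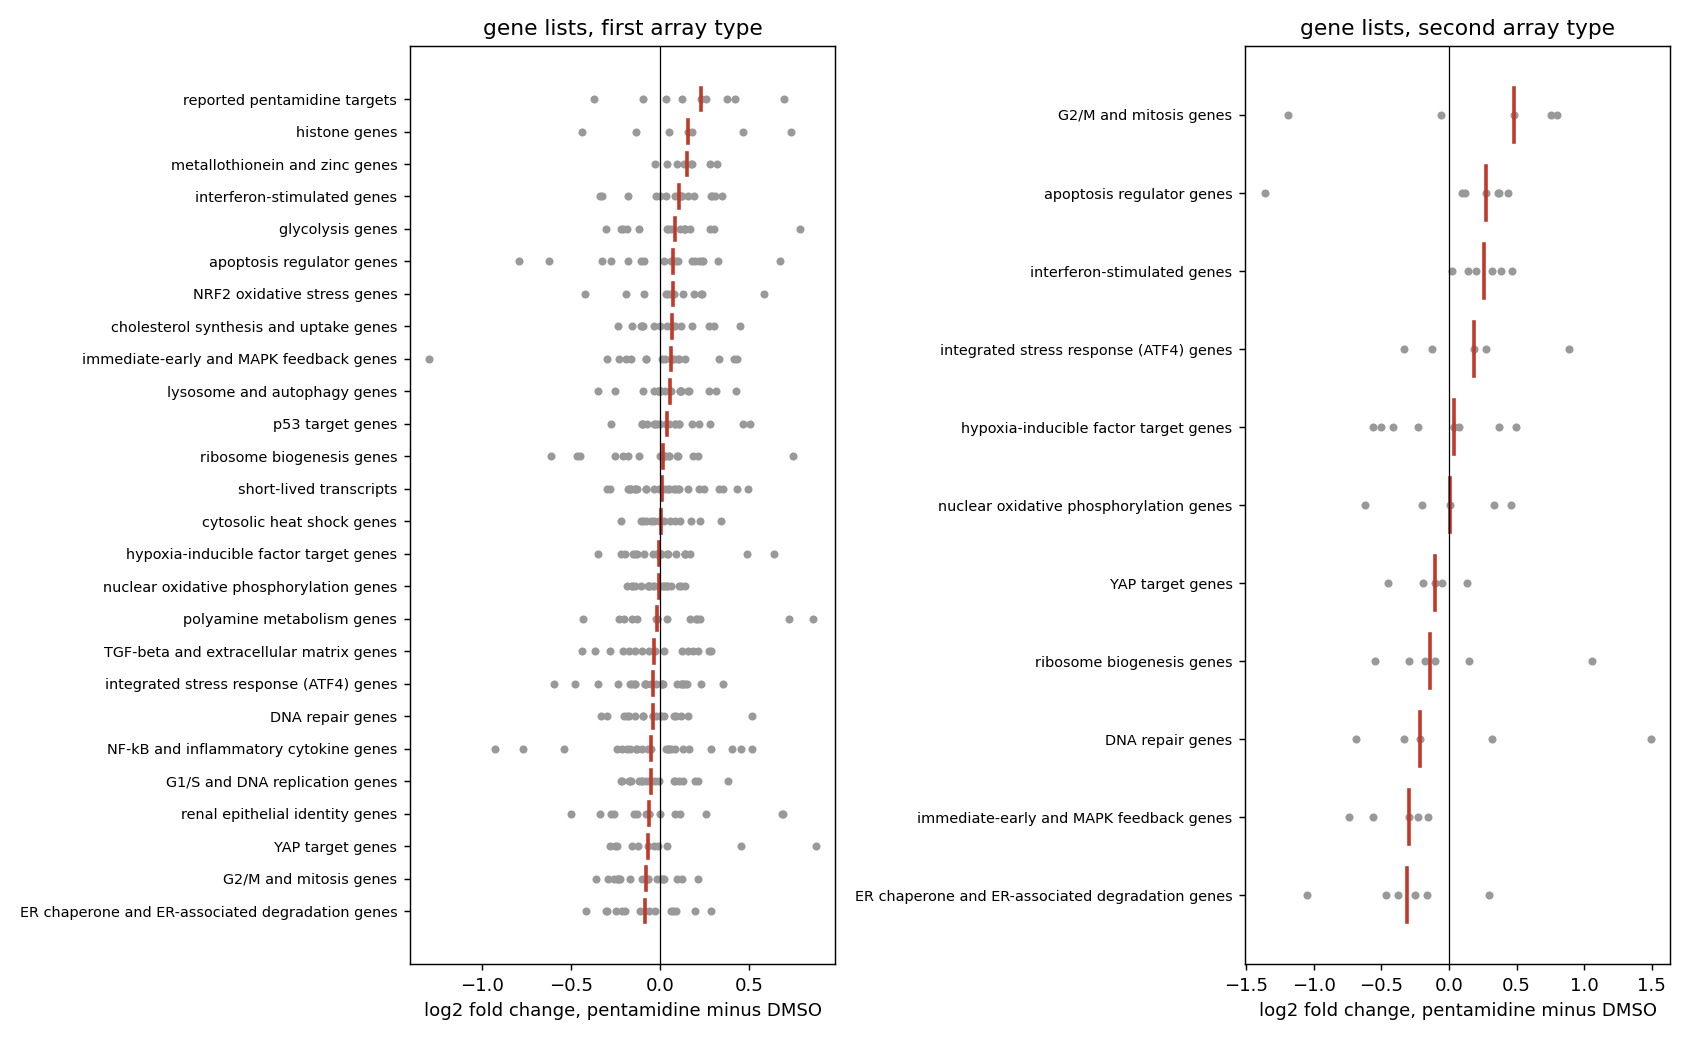
Log2 fold change, pentamidine minus DMSO, of each tested gene (grey points) in each list with at least 5 genes tested, with the list's median as a red line. List medians lie between -0.08 and 0.23 on the first array type and between -0.31 and 0.49 on the second, and no list was called.

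The second comparison put the same question to the second array type, whose probe sets are mostly other ones. Again no gene passed the fixed test. All 5 measured immediate-early and MAPK feedback genes lay below DMSO, with a median log2 fold change of -0.30: EGR1, an immediate-early transcription factor, had -0.74 (95% interval -1.69 to 0.20, n = 2 per group), PHLDA1 -0.56, KLF6 -0.30 and SPRED1 -0.23. All 6 interferon-stimulated genes lay above DMSO (median 0.26), with OAS2 at 0.47, RIGI at 0.39, IFIT3 at 0.32 and IFIT2 at 0.20. On this array type the 3' to 5' ratio of all 3 RNA quality controls was also lower in both pentamidine arrays than in both DMSO arrays. With 2 arrays per group this may be chance, and on the first type the groups overlapped. A difference in RNA quality cannot be told apart from treatment on these arrays. Of 15804 probe sets tested with limma, 0 passed, with a smallest adjusted p of 0.395. An unadjusted p under 0.05 was reached by 1113, where chance gives 790.2, 619 of them above and 494 below DMSO. With a variance trend the count was 806, near the chance number, and with a 50th percentile filter it was 520 of 11289. Without pentamidine array 1 the direction turned, to 413 above and 773 below, and without pentamidine array 2 to 560 above and 809 below.

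The 12 genes named by rule were dim, so their fold changes depend on the offset, and none passed, each with a limma adjusted p of 0.395. SKIL, a repressor of TGF-beta signalling, measured 11.7 and 14.1 units in DMSO and 244 and 229 in pentamidine (log2 fold change 3.13, 95% interval 2.29 to 3.97, or 0.69 to 5.56 with a variance trend), while its probe set on the first array type gave 0.29. With an offset of 1 the value for SKIL was 4.10 and with a larger one 1.37. APOC3, XRCC5, OR51B2, DLGAP3 and DIPK1B lay above DMSO by log2 fold changes of 2.46 to 3.20, while XRCC5 had -0.08 on the first array type. ERICH6 measured 206 and 205 units in DMSO and 12.1 and 10.2 in pentamidine (log2 fold change -3.03, or -1.26 with a larger offset), and TRAJ17, TUB, FAM228A, ZNF141 and SLAIN1 had values from -2.84 to -2.63, while ZNF141 had 0.08 on the first array type.

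Other lists had few measured members. ER chaperone genes lay above DMSO in 1 of 6 (median -0.31), with SEC61B at -1.05. G2/M genes lay above in 3 of 5 (median 0.49, mean 0.16), with CDK1 at 0.80, AURKB at 0.76 and TOP2A at -1.19. On the first array type CDK1, AURKB and TOP2A had -0.07, -0.24 and 0.12 by other probe sets. SEC61B and TOP2A were dim here, with 95% intervals of -3.42 to 1.325 and -3.85 to 1.46. Other probe sets named below were dim too, among them those of CASP9, NBN and PES1. Apoptosis regulators lay above in 6 of 7 (median 0.27), with XIAP at 0.44 and CASP9, an initiator caspase, at -1.36. ATF4 genes lay above in 3 of 5 (median 0.19), with JDP2 at 0.89, hypoxia-inducible factor targets in 5 of 9 (median 0.03, mean -0.08), with ALDOA at -0.50, and YAP targets in 1 of 5 (median -0.10), with CRIM1 at -0.19. DNA repair genes lay above in 2 of 5 (median -0.22, mean 0.12), with MRE11 at -0.69 and NBN at 37.4 and 57.6 units in DMSO and 236 and 108 in pentamidine. Ribosome biogenesis genes lay above in 2 of 6 (median -0.14, mean 0.01), with PES1 at 1.06 and NIP7 at -0.55, and oxidative phosphorylation genes in 3 of 5 (median 0.01), with UQCRC2 at -0.62. No gene passed in the fixed fit when adjusted over the list alone, while PHLDA1 at 0.0247 and NIP7 at 0.0259 did in the limma fit with a variance trend. No list of 11 was called by limma's camera: the lowest adjusted p was 0.176, for the immediate-early list, and 0.900 with an estimated correlation.

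With the variance trend, limma called 1 probe set of the second array type, 238199_x_at, for which the annotation used here lists no gene. It measured 7202 and 6895 units in DMSO and 3073 and 1709 in pentamidine, a log2 fold change of -1.61 (95% interval -2.02 to -1.21, adjusted p = 0.000202). In the fit fixed beforehand its interval was -2.83 to -0.40 and its adjusted p 0.536. CLDN12, a tight junction protein, came next without passing, at -0.88 and an adjusted p of 0.0659. In simulated data, the fixed fit found 0% of changes of 2-fold to 8-fold on this array type and the trend fit 15.2% of 2-fold and 66.9% of 8-fold changes among above-median probe sets. A list shifted by 0.5 was called in 14 of 20 simulations, again with genes drawn independently.

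**Figure D3:**
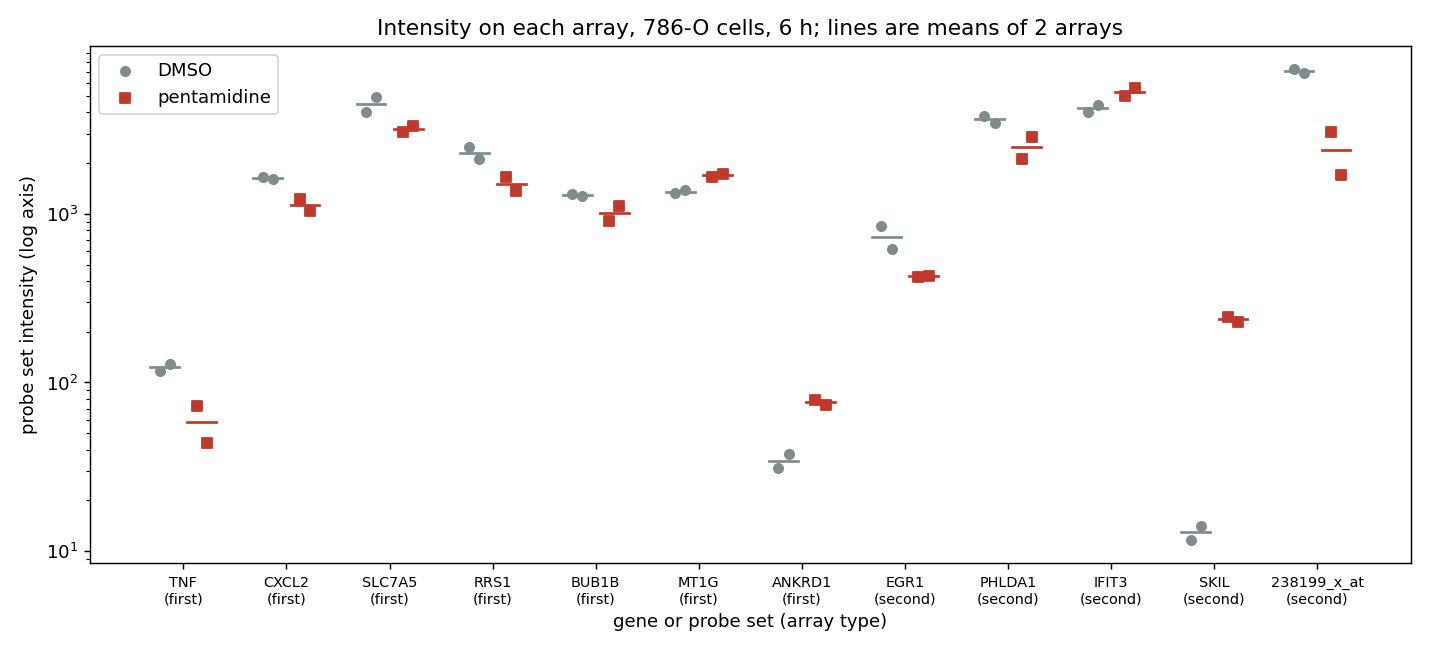
Intensity on each array, on a log axis, of genes from the lists and of 238199_x_at, with grey circles for DMSO, red squares for pentamidine and lines for the means of 2 arrays. The DMSO and pentamidine arrays do not overlap for these genes, which are among the members with the largest moderated t of their lists. Their separation is therefore no test. Over all probe sets tested, 35.2% on the first type and 34.2% on the second do not overlap, where chance gives 33.3%. Only 238199_x_at passed over all probe sets, in the trend fit, at a log2 fold change of -1.61.

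The third comparison set the 2 array types side by side over 2701 genes measured by different probe sets on both. The fold changes were almost unrelated: across genes, which are not independent replicates, Pearson's r was 0.0499 and Spearman's rho 0.0429, and 50.98% had the same sign. CXCL2 had -0.54 on the first type and 0.60 on the second, PDK1 0.49 and -0.56, and EGR1 -0.16 and -0.74, genes picked after their values were seen. Of 54 genes at least 1.5-fold from DMSO on both types, 35 had the same sign, and among genes above the 50th percentile on both it was 3 of 4. The 100 gene probe sets that both array types carry in common gave r = 0.409. Over the same probe sets, the difference between the DMSO arrays gave r = 0.154 between the types. That between the pentamidine arrays gave 0.184.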

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

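All tests in this part were chosen after the result was seen. Control probe sets on the arrays, which no comparison used, carried a signal above DMSO on both array types. The 3' probe set of the HUMRGE control, for which the annotation lists no gene, was 2.85-fold higher in pentamidine on the first type, at 138 and 282 units in DMSO against 511 and 695. It was 2.74-fold higher on the second, at 745 and 1526 against 3035 and 2876. The 5' probe set was 2.18-fold and 2.14-fold higher. The middle probe set was 2.83-fold and 2.17-fold higher, but on the second type its lowest pentamidine array, at 3145 units, lay under the highest DMSO array, at 3416. The 5' probe set of another control, M27830, had a like pattern, 1.988-fold and 1.545-fold higher. DMSO array 1 was again the lowest there, at 321 units on the first type and 2121 on the second. Of 62 control probe sets on both types, 9 were higher in both pentamidine arrays on both, where 1.72 would be expected if the types were independent. Of the 9, 2 were higher by at least 2-fold on both. Several of the 9 measure the same transcript, ACTB and GAPDH among them, so they are not 9 separate signals. Those of ACTB and GAPDH are bright. The brightest 2% of tested probe sets leaned upward on the first type (median log2 fold change 0.14) but not on the second (0.00).

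A scaling shift common to all probe sets is argued against, since the median log2 difference of all tested probe sets was 0.0244 or less in size on both types. Arrays with equal trimmed means leave little room for such a shift. That median cannot decide on scaling that depends on level, and the control probe sets were not normalized again, so such scaling stays open. Spread between arrays of 1 group stays open: the DMSO arrays differed by at least 2.04-fold, more than the gap of up to 1.89-fold between the groups. The difference between the DMSO arrays had r = 0.61 between the types over the 62 control probe sets and 0.15 over the 100 shared gene probe sets, and that between the pentamidine arrays 0.26 and 0.18. Whether the types share RNA is not given in the sources used here, so the second type is not counted as an independent repeat. An effect of pentamidine also stays open and was not tested apart from that spread.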

How the results depend on the processing

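On the first array type no probe set and no list passed under any alternative run, with 617 to 1339 probe sets at an unadjusted p under 0.05 in limma when 1 array was left out, the 1339 without DMSO array 2. On the second type the count was 0 except with a variance trend. It was 1 with the trend, 1 with the trend and a 60th percentile filter, and 2 with the trend and a robust prior, the last pair of settings chosen after seeing the data. The calls were 238199_x_at in all 3, and CLDN12 in the last. The log2 fold change of 238199_x_at ranged from -1.19 to -2.03 over all settings and its adjusted p from 0.000105 to 0.865. The trend ends the pooling of the variances of dim and bright probe sets, whose median residual SD was 0.99 and 0.26.

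With the 60th percentile filter, also chosen after seeing the data, 1 list was called on the second type, the immediate-early genes, at an adjusted p of 0.0432. The call was lost with an estimated correlation, at 0.637 with that filter and 0.900 with the 30th percentile, the ends of the range over settings being 0.0432 and 0.900. The filter leaves 7 lists in the adjustment in place of 11. With the replicate number as a block, 0 probe sets and 0 lists passed on either type, with 752 and 1053 probe sets at an unadjusted p under 0.05. Same-numbered arrays deviated together with r = 0.00 and 0.01, so the numbers show no pairs. Leaving out 1 array gave 0 calls on both types, the lone array assumed to vary like the other group. On the second type the fixed fit found 0% of simulated changes up to 8-fold, so its 0 calls there, with a block or an array left out, say nothing about stability. The named genes kept their sign in all 458 alternative values and none passed. They were picked for groups that do not overlap, so leaving out an array or changing the offset could not turn the sign. Genes that a stricter filter removed gave no value there. The 458 values therefore say little about stability. Of 501 list medians or tests, 462 kept sign and side, 38 changed sign and 1 passed. Dim probe sets were measured less precisely: the 95% interval of the trend fit lay inside a 2-fold change for 42.8% of those below the median on the first type and 0% on the second.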

Other observations

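The trend fit, the alternative scalings, leaving out each array and the count of splits for the trend fit were planned. The bounds set for leaving out an array and for scaling, the list-alone adjustment within the trend fit, the count of splits at an unadjusted p and the test on immediate-early genes were chosen after the results were seen. Ranked by the trend fit of limma, which does not let dim probe sets set the variance of bright ones, several bright genes, chosen here after their values were seen, stood apart from DMSO without passing over all probe sets. On the first array type EREG, an EGF receptor ligand, had a log2 fold change of -0.57, the host RNA SNHG32 -0.66, the protease ADAMTS1 -0.59 and the lipolysis inhibitor G0S2 0.47. On the second, CLDN12 had -0.88, GNA12, a G protein subunit, -0.66 and NFKBIZ, an NF-kB cofactor, -0.50. Genes of that ranking were mixed between the types, by other probe sets. GNA12 kept its sign on the first type, at -0.34, and ADAMTS1 on the second, at -0.28. WASF2 had -0.42 on the first type and 0.56 on the second, and RIPK4 -0.62 and 0.18. Adjusted over the list alone in the trend fit, RRS1 passed at 0.0155, NOP56 at 0.0477, SLC7A5 at 0.0458 and CXCL2 at 0.0495 on the first type, and NIP7 at 0.0259 and PHLDA1 at 0.0247 on the second. All 6 were lower in both pentamidine arrays than in both DMSO arrays, which their choice by a small p makes likely. By other probe sets, CXCL2 went the other way on the second type, at 0.60, NIP7 on the first, at 0.10, and PHLDA1 lay at 0.01 on the first. The other 3 were not tested by other probe sets on the second type.

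The bright probe set 238199_x_at was lower in pentamidine on the second array type. No single array accounts for it, since the log2 fold change stayed at -1.19 or further from 0 when any 1 array was left out. Scaling is argued against by -1.57 after quantile normalization. The trend fit called 1 probe set in the real split of the arrays and at most 2 in the others, with 2 of 3 splits, the real one included, giving at least 1, and 3 splits are too few for a share under 0.05. An effect of pentamidine on its transcript stays open, and the annotation names no gene for it.

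On the second type, 1113 probe sets had an unadjusted p under 0.05, where chance gives 790.2, but with the variance trend the count was 806. Without the trend the highest count of the other splits was 1177. Counting the real split, 2 of 3 splits gave at least 1113, again too few splits for a share under 0.05.

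A hypothesis was that pentamidine lowers immediate-early genes, all 5 of which lay below DMSO on the second type. EGR1, PHLDA1, KLF6 and ETV5 were also measured by other probe sets on the first type, where their median log2 fold change was 0.0372 against -0.43 on the second. Their mean there was 0.00 with an SE over genes of 0.06, and 1 of the 4, EGR1, lay below DMSO. That SE runs over genes measured on the same arrays, so it does not measure the spread between arrays or cultures. The fall on the second type was thus not seen in these 4 genes as a set on the first. Fold changes of the same genes were almost unrelated between the types (Pearson's r 0.0499), so these values cannot decide the hypothesis. EGR3 of the same list had -1.30 on the first type, from a dim probe set, while 12 of the list's 19 genes lay above DMSO there. The list was called only with a filter added after the data were seen, at 0.0432, and with an estimated correlation at that filter it was not, at 0.637.

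The 3' to 5' log2 ratio of control probe sets, a sign of RNA quality, was lower in both pentamidine arrays than in both DMSO arrays for all 3 controls on the second type. For GAPDH it was -0.25 and -0.31 in DMSO and -0.48 and -0.56 in pentamidine. For ACTB it was 0.56 and 0.35 against 0.29 and 0.27, and for the HUMISGF3A control 2.23 and 1.45 against 1.11 and 1.34. On the first type the groups overlapped for all 3, from -0.28 to -0.05 for GAPDH, from -0.00 to 0.29 for ACTB and from 1.17 to 1.93 for HUMISGF3A.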
